A study of Homo sapiens with 3 samples.

How the data were processed

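Chromatin immunoprecipitation sequencing was done on HCT116 cells expressing Flag-tagged VCP, with 1 library for an antibody to VCP, 1 for an antibody to Flag and 1 for input. Per the labels' protocols, cells were fixed for 10 minutes in 1% formaldehyde, chromatin was digested with micrococcal nuclease, and libraries were made from 10 ng of DNA with 8 amplification cycles and size selection between 250 and 450 bp. Per the submitters' processing notes, the tools included bcl2fastq 2.17, Trimmomatic 0.33, Bowtie 1.1.2 and MACS2 2.1.0, and the build was hg38. Their settings are not given in the sources used here. The peak lists of the VCP and Flag libraries were used, and reads or signal of the input were not used here.

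Each deposited list gives a position, a summit, a score, a fold enrichment, and -log10 of p and of q per peak. The fold enrichment is the authors' ratio of the reads at the summit over the local background. The -log10 p and -log10 q values are the authors' and come from the peak caller. The deposited score equals 10 times -log10 p, rounded down, in all 1816 and 5719 peaks, and was not used further. The lowest -log10 p was 3.00 in both deposited lists, so they appear to hold peaks selected on the unadjusted p, and their median q was 0.416 in the VCP list and 0.106 in the Flag list. Fold enrichment and -log10 q were used to rank, filter, describe and test peaks within a list and were not tested between lists. The reads and backgrounds derived from fold enrichment and p were also set side by side for both lists. Peaks were called per library, and nothing could be averaged over replicates.

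Depth was read from the lists themselves, by a step chosen after the data were seen. For each peak the whole number of reads was sought whose Poisson tail, with a background set by the fold enrichment and a pseudocount of 1 read, came nearest to the authors' -log10 p. All peaks matched within 0.001, while 1.05% of VCP peaks and 1.08% of Flag peaks matched after the -log10 p was shifted at random. Reads at a summit have exact Poisson intervals, and shares have exact binomial (Clopper-Pearson) 95% intervals. Both cover counting error only, since reads amplified by PCR are not independent molecules.

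Gene positions came from a RefSeq gene table of GRCh38.p14, the same build. Of its 59792 rows, 58961 were kept on chromosomes 1 to 22, X and Y, leaving out rows whose coordinates belong to other scaffolds, and 19866 of those kept were protein-coding. The table has no strand, so the promoter results fixed in the design were measured as a summit within 1 kb of either end of a protein-coding gene. This measure therefore also counts peaks at transcript ends. Only the outer ends of each gene were used, so starts of other transcripts inside a gene counted as its body. A genome sequence was not used here, so the motif tests and the alternatives that leave out repeats were not run.

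Peaks were compared between the lists by an overlap of at least 1 bp. Random placement kept each peak on its chromosome with its width and drew its summit from the 2873 Mb between the first and last gene of each chromosome, without 24 gene-free stretches longer than 2 Mb, which stand in for gaps in the assembly. Each test used 10000 placements. Medians were compared by permutation with 100000 resamples, or exactly where the splits were fewer. Shares, gene overlaps and gene lists were compared by Fisher's exact test, with Benjamini-Hochberg adjustment over the 21 gene lists and a threshold of 0.05. Of the lists, 17 were written by member (590 symbols, of which 590 matched) and 4 by symbol pattern. The background was all 19866 protein-coding genes, whether or not they are expressed in these cells.

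The groups, tests, gene lists, rule for named genes and most alternatives were chosen before the data were examined. The use of either gene end in place of the start, the bounds of placement and the 3 alternatives named as later in the sensitivity part were set once the files had been seen. Named genes were, per list, the 10 protein-coding genes with the highest -log10 q among peaks at their ends, the 10 genes with such a peak in both lists and the lowest sum of ranks, the VCP gene, and up to 4 members of each reported gene list by -log10 q. Not every gene that this rule picks is named in the text. Named regions were the 5 peaks per list with the highest -log10 q. The alternatives were stricter q thresholds, other overlap rules, equal list sizes, other windows and gene sets, other placement and other measures of strength.

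The code was tested on simulated data. Of 100 random lists of 1000 peaks, 2.00% passed the overlap test at 0.05, and all 100 planted shared peaks were found. Of 100 draws of random genes, 4.00% had any of the 21 gene lists called, and a list with 15 planted members was called in 99.0% of draws. The drawn gene sets were nearer in size to the Flag gene set than to the VCP one, so they do not give the power of the VCP tests. The simulated reads were recovered for 100% of 1000 simulated peaks. Computation used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, with seed 1.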

Results

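The series mapped where VCP meets chromatin in HCT116, a human colorectal cancer cell line that here expressed Flag-tagged VCP. VCP is an ATPase that extracts ubiquitin-tagged proteins from complexes and membranes. Fixed, nuclease-digested chromatin was precipitated with an antibody to VCP or with an antibody to the Flag tag, and an input library was made alongside. Each of the 3 samples was 1 library without replicates, so every p-value below describes the peak lists themselves and not the spread between cultures. The VCP list held 1816 peaks and the Flag list 5719 peaks, and 1803 and 5692 of these lay on the chromosomes and were compared. Coordinates are 1-based on hg38.

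The lists differed in length although their genome-wide backgrounds were alike. The reads at each summit and the local background were recovered from the fold enrichment and p-value of each peak, and came out whole for all 1816 VCP and all 5719 Flag peaks within 0.001 on the -log10 p scale. The lowest background, which grows with the depth and fragment length of a library, was 1.74 reads in the VCP list and 1.85 reads in the Flag list, a ratio of 1.06. The median peak rested on 10 reads at its summit in the VCP list (quartiles 9 and 12) and on 11 reads in the Flag list (quartiles 9 and 13). Most peaks were therefore weak. A q of at most 0.05 was reached by 118 VCP peaks (6.50%, exact 95% interval 5.41 to 7.73) and by 1932 Flag peaks (33.8%, 32.6 to 35.0). Intervals here and below cover counting error only.

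**Figure D1:**
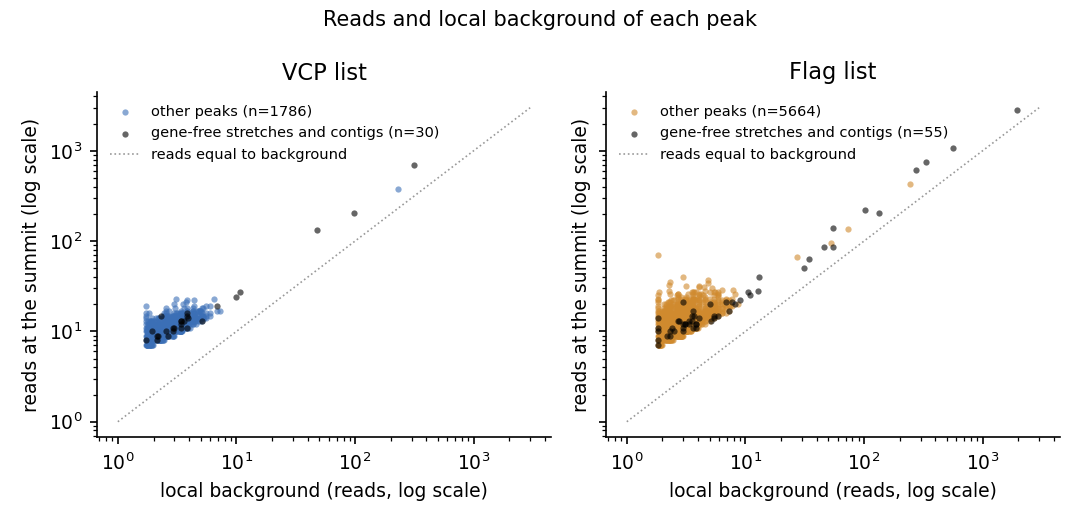
Reads at the summit (vertical, log scale) against the local background in reads (horizontal, log scale) for the peaks of the VCP list (left) and the Flag list (right), with black points for peaks in gene-free stretches and on contigs and a dotted line where both are equal. Median peaks had 10 reads (VCP list) and 11 reads (Flag list) at the summit, and the highest had 702 and 2804 reads over backgrounds of 317 and 1945 reads.

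Whether both antibodies recovered the same sites is the comparison the design implies. The genes with the highest combined rank in both lists were EIF2B4, which encodes a subunit of a translation initiation factor, and its neighbour SNX17, which encodes a sorting nexin. Their shared peak had its summits between them on chromosome 2 and spanned 27370320 to 27370525 in the VCP list (fold enrichment 4.73, 14 reads, 95% interval 7.65 to 23.5) and 27370292 to 27370543 in the Flag list (fold enrichment 6.70, 20 reads, 12.2 to 30.9). GABPB2, which encodes a transcription factor subunit, had summits 121 bp from its end in the VCP list and 148 bp in the Flag list. RNF130, a ubiquitin ligase gene, the autophagy gene GABARAP with its neighbour CTDNEP1, the chromatin scaffold gene BRPF1, the cohesin regulator gene PDS5B and the lysosome positioning gene BORCS7 were also among the genes ranked highest in both lists. At these 9 genes the peaks themselves overlapped.

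In all, 196 VCP peaks overlapped a Flag peak by at least 1 bp, which was 10.9% of the VCP list (exact 95% interval 9.47 to 12.4). Random placement of the VCP peaks on the same chromosomes gave a mean of 2.1 overlaps (SD 1.46, highest 10), so the observed number was 93.3 times the placed mean (n = 1803 peaks, 1-sided p = 0.0001, the smallest that 10000 placements can give). In the other direction 196 Flag peaks overlapped a VCP peak, 3.44% of the Flag list (2.98 to 3.95), against a placed mean of 2.1 (n = 5692 peaks, 1-sided p = 0.0001, again the smallest possible). Placement within the same class of location raised the placed mean to 7.45 and left the VCP overlap 26.3 times above it. The classes were the ends of protein-coding genes, their bodies, and the sequence between them, which includes non-coding genes. Gene bodies here include any transcript start that lies more than 1 kb inside the outer ends. The summits of overlapping peaks lay a median of 78.5 bp apart (quartiles 37.8 and 144 bp). At gene ends 128 of 395 VCP peaks were shared (32.4%, 27.8 to 37.3), in gene bodies 39 of 530 (7.36%, 5.28 to 9.92) and between genes 27 of 861 (3.14%, 2.08 to 4.53). Against placement within the same class the order differed, with 19.9 times the placed mean at gene ends, 98.9 times in gene bodies and 43.6 times between genes.

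**Figure D2:**
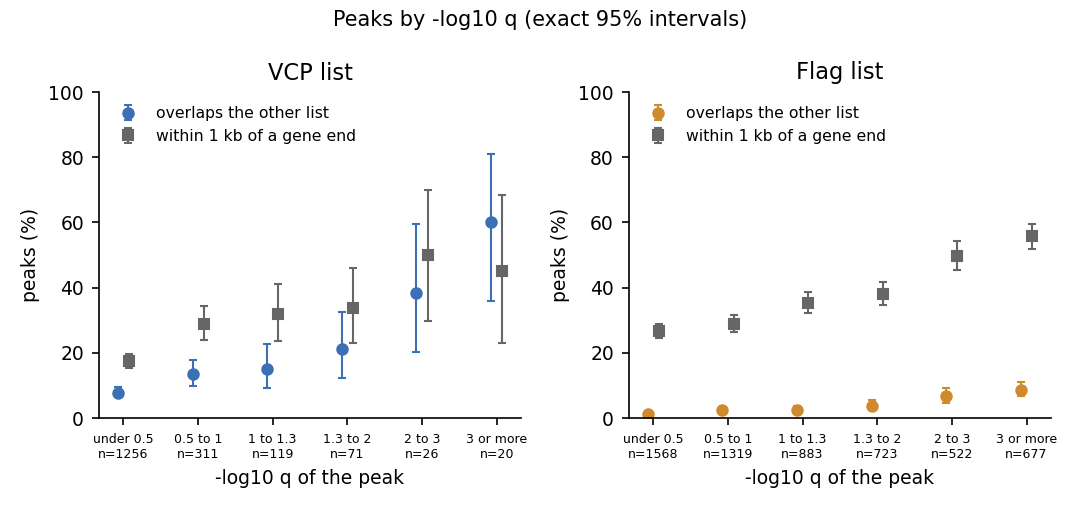
Share of peaks that overlap the other list (circles) and share with a summit within 1 kb of a protein-coding gene end (grey squares), in percent with exact 95% intervals, by the -log10 q of the peak, for the VCP list (left) and the Flag list (right). The overlapping share ran from 7.88% of VCP peaks with -log10 q under 0.5 to 60% of the 20 VCP peaks at 3 or more, and from 1.15% to 8.71% of Flag peaks.

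Shared peaks were the stronger ones within each list by fold enrichment. The median fold enrichment was 3.5 for the 196 shared VCP peaks and 3.25 for the 1607 others, a ratio of 1.08 (permutation test of the median log2 fold enrichment, 2-sided, p = 2e-05). For the Flag list it was 3.95 for the shared peaks and 3.49 for the 5496 others, a ratio of 1.13 (p = 1e-05, the smallest that 100000 permutations can give). With -log10 q in place of fold enrichment the VCP difference was 0.058 and no longer passed the test (permutation p = 0.17). Among Flag peaks with -log10 q of at least 5 the difference in median log2 fold enrichment was -0.027 (permutation p = 0.48).

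Peaks of both lists gathered at the ends of protein-coding genes. The gene table used here carries no strand, so a peak was counted at a gene end when its summit lay within 1 kb of either end. Gene ends held 395 VCP peaks (21.9%, exact 95% interval 20 to 23.9) and 2027 Flag peaks (35.6%, 34.4 to 36.9), against 2.77% and 2.98% of placed peaks (2-sided p = 0.0002 for each list, the smallest possible). Bodies of protein-coding genes and the sequence between such genes held fewer VCP peaks than placement gave, 29.4% against 43.7% and 47.8% against 53.6%. Non-coding genes away from protein-coding ones count as sequence between genes here. Of the shared VCP peaks 65.3% (58.2 to 71.9) lay at gene ends, and of the unshared ones 16.6% (14.8 to 18.5). For the Flag list these shares were 64.8% (57.7 to 71.5) and 34.6% (33.3 to 35.8). The share at gene ends was lower in the VCP list than in the Flag list, with a difference of -13.7 percentage points (Fisher's exact test, 2-sided, p = 1.5e-28). The difference was -8.24 points and did not pass Fisher's exact test (p = 0.087) among peaks with a q of at most 0.05. With the Flag list limited to the size of the VCP list it was -26.8 points (Fisher's exact test, p = 1e-64). That setting kept the Flag peaks with the highest -log10 q and all VCP peaks, so it matched size and not strength. The share at gene ends was higher at high -log10 q in both lists. In the VCP list it was 17.6% under 0.5 and 45% at 3 or more, and in the Flag list 26.7% and 55.8%.

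**Figure D3:**
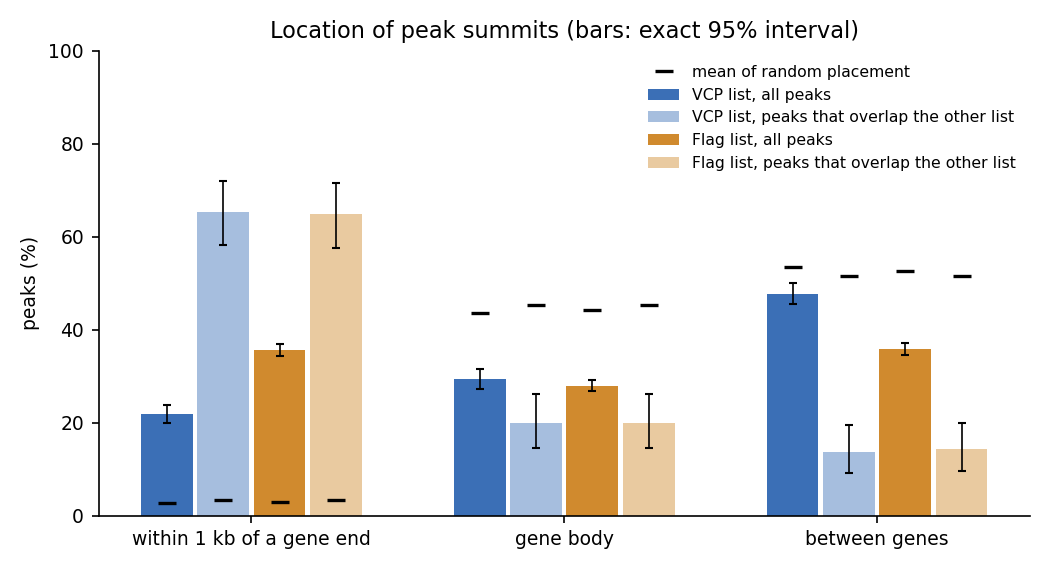
Share of peak summits (percent) within 1 kb of a protein-coding gene end, elsewhere in the body of such a gene, or between such genes (non-coding genes included), for all peaks of each list (dark bars) and for the peaks that overlap the other list (light bars), with exact 95% intervals and the mean of random placement as black marks. Shared peaks lay at gene ends in 65.3% (VCP list) and 64.8% (Flag list), above the 21.9% and 35.6% of all peaks.

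Among the genes named by the VCP list, ARMH3 on chromosome 10 had the peak with the highest -log10 q at a gene end (102056022 to 102056244, fold enrichment 5.85, -log10 q 6.94, 23 reads over a background of 3.10). A peak on chromosome 7 (143381304 to 143381517, fold enrichment 6.20) lay 101 bp from the end of ZYX, which encodes the focal adhesion protein zyxin, and 858 bp from that of FAM131B. UBB, a polyubiquitin gene (fold enrichment 5.04), and SLC35B1, a nucleotide transporter gene (4.74), were also among the 10. A peak with a fold enrichment of 4.85 on chromosome 1 lay 159 bp from the end of EMC1, a membrane protein insertase gene, and 122 bp from that of MRTO4, which ties with EMC1 in -log10 q and is named here after its values were seen. GABPB2, the zinc finger gene ZNF76 (fold enrichment 5.32), PGM2L1 (5.47) and NFKB2, a subunit of NF-kappa-B (4.72), completed them. The peaks of 6 of these 10 genes overlapped a Flag peak. ARMH3, SLC35B1 and NFKB2 lie on segments that are compared below as copy gains. Away from the outer gene ends, the autophagy gene ATG101 held a VCP peak in its body on chromosome 12 (52069722 to 52070014, fold enrichment 7.30, 19 reads), which the Flag list shared. Transcript starts inside genes were not mapped, so a promoter at this peak is not excluded.

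In the Flag list ARRDC4, which encodes an alpha-arrestin, had the peak with the highest -log10 q and fold enrichment at a gene end. It spanned 97960312 to 97960697 on chromosome 15, with its summit 212 bp outside the gene, a fold enrichment of 25.3, -log10 q of 76.0 and 71 reads (95% interval 55.5 to 89.6) over a background of 1.85. The next were ADIRF and LOC124902474, which share 1 peak on chromosome 10 (86970985 to 86971573, fold enrichment 10.9, 35 reads), and the neighbours FAM200A and ZNF655 on chromosome 7 (99558304 to 99558806, fold enrichment 10.4, 33 reads). COQ2, an enzyme of coenzyme Q synthesis (fold enrichment 9.70), the cell adhesion gene NECTIN3 (8.87), CLTC, the clathrin heavy chain gene (6.51), and the neighbours ITPRIP and CFAP58 (5.99) followed. These 10 genes rested on 7 distinct peaks, and 0 of the 7 overlapped a VCP peak. CLTC, ITPRIP and CFAP58 lie on segments that are compared below as copy gains.

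The VCP gene itself, on chromosome 9 from 35056064 to 35072625, had 3 Flag peaks and no listed VCP peak. The summits lay at 35059662 (fold enrichment 5.75, -log10 q 7.46), at 35060431 (3.98, -log10 q 1.83) and at 35072696, 71 bp outside the gene (4.21, -log10 q 1.87). Per the labels the cells overexpressed the tagged VCP, and at the 2 inner summits reads of an introduced copy were not separated from those of the gene.

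At the level of genes, 464 of 19866 protein-coding genes had a VCP peak within 1 kb of an end (2.34%) and 2334 had a Flag peak (11.7%). Both lists marked 196 genes, where independent lists would share 54.5, a ratio of 3.60 and an odds ratio of 5.90 (95% interval 4.86 to 7.17, Fisher's exact test, 1-sided, p = 7.6e-64). These were 42.2% of the VCP genes and 8.40% of the Flag genes. Neighbours that share a peak, such as EIF2B4 and SNX17, count here as separate genes. The VCP list had 395 peaks at gene ends for its 464 genes. The p-value and interval of this test therefore overstate the certainty. Only 1 gene kept a VCP peak with -log10 q of at least 5, so that threshold left 0 genes in both lists.

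Of 21 gene lists, 8 held more genes with a Flag peak than all protein-coding genes did and 2 held fewer (Fisher's exact test, 2-sided, Benjamini-Hochberg over the lists). Genes not expressed in these cells are part of that background. These calls therefore cannot tell a preference for a function from peaks at active gene ends in general. Replication-dependent histone genes led, with 26 of 62 (41.9%, exact 95% interval 29.5 to 55.2, adjusted p = 1.8e-08). They included H4C4 (fold enrichment 6.72), H3C2 (6.84), and H1-4 with its neighbour H2BC5 on 1 shared peak (6.73). Neighbouring histone genes share peaks, and the 26 genes rested on 20 distinct peaks. Splicing factor genes had a peak at 14 genes (n = 40, adjusted p = 0.00057), with DDX5 (fold enrichment 5.97), SNRPE (5.91) and SRSF3 (3.67) among them. DNA repair genes had a peak at 11 (n = 32, adjusted p = 0.0029), with ATR (fold enrichment 4.32), BRCA2 (4.92), MDC1 (4.30) and RAD50 (4.44), and immediate early genes at 10 (n = 28, adjusted p = 0.003), with KLF10 (4.05), DUSP6 (3.86) and JUND (3.01). At a q of at most 0.05 only 1 of the 28 immediate early genes kept a peak (Fisher's exact test, adjusted p = 1), and that call was lost. Ribosomal protein genes followed with 18 (n = 77, adjusted p = 0.011), with RPL11 (fold enrichment 5.62) among them. With each peak counted for 1 gene they had 13 and did not pass (n = 77, adjusted p = 0.098). Genes of oxidative phosphorylation had 12 (n = 45, adjusted p = 0.012), with UQCRC2 (6.06) and COX5A (5.27). Proteasome genes had 10 (n = 36, adjusted p = 0.016), with PSMB1 (4.52) and PSMD4 (4.03), and heat shock genes 7 (n = 22, adjusted p = 0.022), with the chaperonin genes HSPD1 and HSPE1 on 1 shared peak (4.91) and AHSA1 (5.11). The proteasome call was lost at a q of at most 0.05, with 4 genes (n = 36, adjusted p = 0.24). At -log10 q of at least 5 the histone genes alone passed, with 6 genes (n = 62, adjusted p = 9.9e-05).

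Olfactory receptor genes had 2 with a Flag peak where 45.7 were expected (n = 389, adjusted p = 2.1e-17), and keratin-associated protein genes 0 where 11 were expected (n = 94, adjusted p = 0.0001). The other 11 lists did not pass the test in the Flag list: DNA replication (8 of 40), NF-kappa-B targets (5 of 20), p53 targets (4 of 28), VCP cofactors (4 of 31), cholesterol synthesis (4 of 24), WNT targets (3 of 22), intestinal epithelium (3 of 21), unfolded protein response and ERAD (2 of 32), HOX clusters (2 of 39), zinc finger genes (56 of 510) and markers of other cell types (0, n = 30, adjusted p = 0.082). Among the VCP cofactors with a Flag peak were UFD1 (fold enrichment 4.54) and NSFL1C (4.30). The UFD1 peak is also counted for its neighbour CDC45, and its summit lay 102 bp from the end of CDC45 and 375 bp from that of UFD1. With each peak counted for 1 gene, 2 of the 31 VCP cofactors had a Flag peak.

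In the VCP list 0 of the 21 lists held more genes with a peak after adjustment, and 4 did at an unadjusted p under 0.05. These 4 were ribosomal protein genes (6, n = 77, adjusted p = 0.075), NF-kappa-B targets (3, n = 20, adjusted p = 0.075), oxidative phosphorylation (4, n = 45, adjusted p = 0.11) and the unfolded protein response with ERAD (3, n = 32, adjusted p = 0.16). NFKB2 (fold enrichment 4.72), RPL17 (4.20) and ATP5PB (4.38) were among their members. In this order the counts were 3.34, 6.42, 3.81 and 4.01 times the expected ones, against 1.99, 2.13, 2.27 and 0.532 times in the Flag list. The VCP set held 464 genes against 2334 in the Flag set. A list that did not pass was therefore not shown to lack enrichment. Olfactory receptor genes had 1 where 9.09 were expected (n = 389, adjusted p = 0.039). This call passed with the 3 kb window (n = 389, adjusted p = 0.0029) and was lost in the other 4 alternatives: the 500 bp window (adjusted p = 0.077), each peak counted for 1 gene (adjusted p = 0.082), and both stricter q thresholds. VCP cofactors (0 of 31), immediate early genes (0 of 28), WNT targets (0 of 22), cholesterol synthesis (0 of 24), intestinal epithelium (0 of 21), markers of other cell types (0 of 30), keratin-associated protein genes (0 of 94) and HOX clusters (0 of 39) had no gene with a peak. Histones (1 of 62), proteasome (1 of 36), heat shock (1 of 22), DNA replication (1 of 40), splicing factors (1 of 40), p53 targets (2 of 28), DNA repair (2 of 32) and zinc finger genes (12 of 510) did not pass. When the composition of the VCP and Flag gene sets was compared list by list with Fisher's exact test, 0 of 21 lists differed after adjustment and 1 differed at an unadjusted p under 0.05 (unfolded protein response and ERAD, p = 0.035, adjusted p = 0.73). The sets share 196 genes, 42.2% of the VCP set, which enter both sides of this test. Its p-values assume separate groups, and the shared genes pull the sets together.

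**Figure D4:**
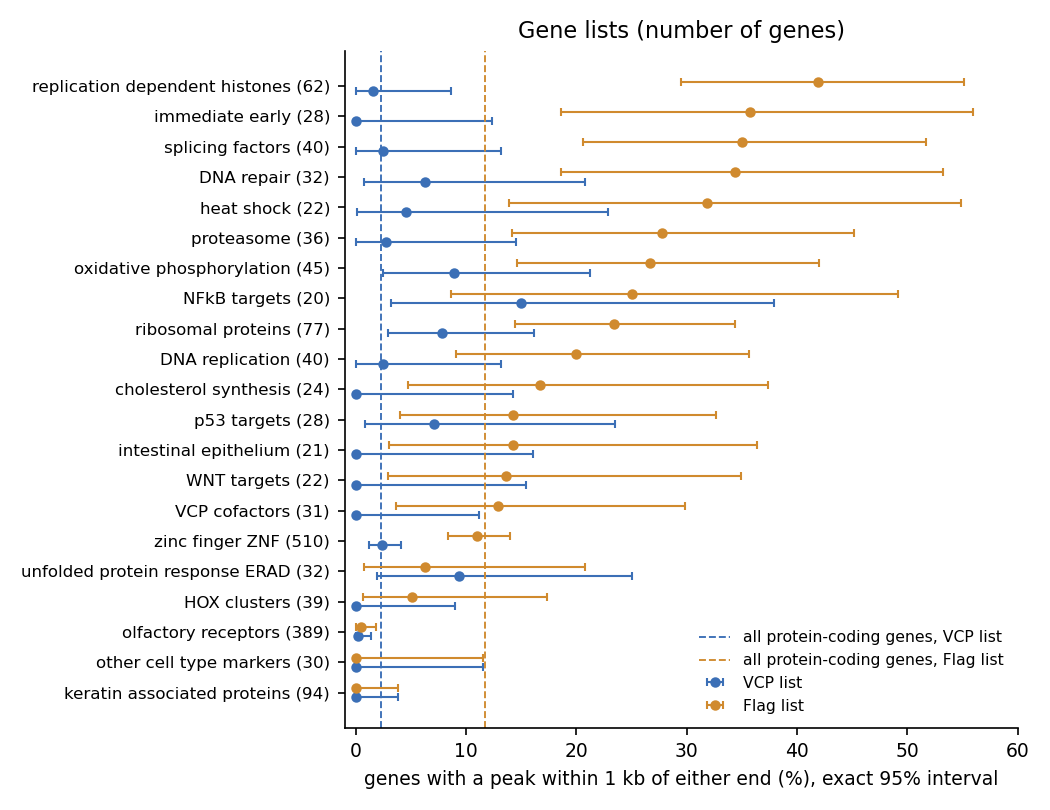
Share of the genes of each list with a peak within 1 kb of either gene end (horizontal, percent, with exact 95% intervals) in the VCP list (blue) and the Flag list (orange), with dashed lines at the shares of all protein-coding genes, 2.34% and 11.7%. Histone genes reach 41.9% in the Flag list, and olfactory receptor genes lie at 0.514% there.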

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

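Peaks on contigs outside the chromosomes were not used in the comparisons, and they were listed above the 3 counts that an empty set allows: 13 in the VCP list, on 11 contigs, and 27 in the Flag list, on 22 contigs. Of these, 6 contigs held peaks in both lists, and 2 of the peaks overlapped between the lists.

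Several of the peaks with the highest -log10 q had low fold enrichment and lay on contigs or in stretches without genes. The VCP list was led by a peak on chromosome 16 at 46390602 to 46390791 (fold enrichment 2.21, 702 reads over a background of 317), followed by chromosome 17 at 26881279 to 26881474 (2.72) and contig GL000216.2 (2.08). In the Flag list the same site on chromosome 16 (2.20, 742 reads over 336) was followed by contig KI270467.1 (1.89), chromosome 3 at 93470468 to 93470686 (1.44) and chromosome 1 at 125180082 to 125180264 (2.22). The backgrounds printed here were recovered from the fold enrichment and p of the same peaks, so they restate the low fold at high significance. Repeats that the assembly holds in too few copies were not tested as the source.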

How the results depend on the processing

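The alternatives with a q of at most 0.05, without gained segments, and with each peak counted for 1 gene were chosen after seeing the data. Of 64 alternative values for 12 results, 52 kept their direction and their side of the threshold or stayed within 1.5 times the count. Some could hardly change: both directions of overlap gave the same counts, and lists with more VCP genes stayed at 0, even with 1 gene left. All 8 alternatives for each overlap were among the 52, with shared peaks from 3 (-log10 q of at least 5 in both lists) to 198 (all sequences). The shared part of the VCP list, 10.9% in the main setting, was 60% at -log10 q of at least 5. It was 23.9% at a q of at most 0.05 and 6.66% with the Flag list limited to its size. At a q of at most 0.05 the Flag share was 1.46%. At -log10 q of at least 5 the VCP list kept 5 peaks on the chromosomes, which limits that setting by construction. Among the 5 were the low-fold peaks flagged above on chromosomes 16 (fold enrichment 2.21) and 17 (2.72). Another lay on chromosome 16 at 34588034 to 34588336 (1.66). In this setting the VCP share at gene ends was 20% (random placement, p = 0.33) and the VCP minus Flag difference -35.7 points (Fisher's exact test, p = 0.18). Genes in both lists were 0, gene lists with more Flag genes 1, and lists with fewer genes 0 in each list. Under it the Flag difference in log2 fold enrichment of shared and unshared peaks was -0.027 against 0.18, and the VCP one had no value, as all 5 peaks were shared. The VCP minus Flag difference was -8.24 points (Fisher's exact test, p = 0.087) at a q of at most 0.05, where 117 VCP peaks were left. The VCP difference between shared and unshared peaks was 0.058 (permutation test, p = 0.17) with -log10 q in place of fold enrichment. The VCP call of fewer olfactory receptor genes dropped to 0 lists with the 500 bp window, a q of at most 0.05, or each peak counted for 1 gene. Except where list size sets it, the cause was not tested. For the named genes ranked by their peaks, the window decides only whether a peak is left, and within 500 bp FAM131B (VCP list), CTDNEP1 (both lists), ADIRF and RNF130 (Flag list) had none. Named members of gene lists were not run one by one. Motif tests and the repeat alternatives were not run. A site missing from a list was not shown to be unbound. No paired analysis was possible because each antibody has 1 library.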

Other observations

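The tests of gene ends by orientation, of gene classes and of the VCP gene in this part were chosen after the data were seen. For genes with a named divergent transcript, that transcript shows at which end the gene starts. Among 529 such genes, the VCP list had a peak within 1 kb of the end facing the divergent transcript at 17 genes and at the opposite end at 0 (exact binomial test, 2-sided, p = 1.5e-05), and the exact 95% interval of 0 of 529 reaches 0.695%. The Flag list had a peak at the divergent end of 92 genes (17.4%, exact 95% interval 14.3 to 20.9) and at the opposite end of 3 (p = 7.2e-24).

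Flag peaks also lay near small RNA genes. Within 1 kb of a tRNA gene there were 54 Flag peaks, 30.8 times the placed mean of 1.75, and 7 VCP peaks, 14.4 times the placed mean of 0.486 (n = 5692 and n = 1803 peaks, 2-sided placement p = 0.0002 for each). Of these, 40 Flag peaks and 4 VCP peaks were not at the end of a protein-coding gene. By -log10 q the strongest lay on chromosome 1 at 146037728 to 146038372 (-log10 q 5.37, fold enrichment 5.89), over TRH-GTG1-1 and beside TRG-TCC2-1. The next lay on chromosome 6 at 28943533 to 28943755 (4.27, fold enrichment 4.33). Near snRNA genes there were 14 Flag peaks (14.6 times the placed mean, n = 5692, p = 0.0002) and 3 VCP peaks (11.9 times, n = 1803, p = 0.005), of which 8 and 2 were away from protein-coding gene ends. Near snoRNA genes the 15 Flag peaks were 3.09 times the placed mean (n = 5692, p = 0.0004), while 2 VCP peaks were 1.34 times it (p = 0.9), and 10 and 0 of them were away from protein-coding gene ends. Pseudogenes had 62 Flag peaks against 85.4 placed (n = 5692, p = 0.009) and 22 VCP peaks against 26.3 placed (n = 1803, p = 0.5). The lists were not tested against each other for these classes. At the VCP gene, 2 Flag peaks lay over 1 kb inside both ends, and 6 of 2509 protein-coding genes of similar length (0.239%, the VCP gene included) had as many. DNA of an introduced VCP copy and binding at these 2 inner peaks cannot be told apart here. So many inner peaks are rare, as that DNA would predict, but the VCP list, which it would raise too, had no peak inside the gene, and exon positions were not used here.

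Peaks away from gene ends were unevenly spread along chromosomes. The segments compared here, distal 8q, 10q and 17q, are copy gains of the HCT116 karyotype written from memory. They were named after totals per chromosome had been seen and before densities within chromosomes were computed, and the test of their background was added once those densities were known. Several genes named above lie there, such as ARMH3, NFKB2, BORCS7, SLC35B1, CLTC, ITPRIP and CFAP58. Their peaks at gene ends are not among the peaks compared here. Whether extra copies raised the peaks of these genes was not tested. The segments held 1.1 VCP peaks per Mb against 0.552 on the rest of the same chromosomes, a rate ratio of 1.99 (exact 95% interval 1.55 to 2.56), and for Flag peaks the ratio was 2.23 (1.89 to 2.64). Protein-coding gene ends were 1.14 times denser there, below the lower bound of the VCP ratio, which argues against gene density as the whole source. The median local background of these peaks was also higher on the gained segments, by 1.29 times for VCP peaks (permutation p = 0.0026) and 1.23 times for Flag peaks (p = 1e-05). Extra DNA copies are consistent with both values, and binding that differs between the segments was not tested.

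The tests of the overlap were chosen after the overlap itself had been seen. Without gained segments, contigs and gene-free stretches, 160 VCP peaks still overlapped a Flag peak, 96.0 times the mean of placements outside those places (n = 1561 peaks, 1-sided p = 0.0001), so those places do not account for it. Input reads used in both calls, which would lift the same sites where the input is thin, were not tested as a source and stay open. Recovery of active promoters by any antibody cannot be told apart from VCP at those sites, because 0 peak lists of a control antibody or of untagged cells were analysed here.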
